A study of Homo sapiens and Mus musculus with 14 samples.

How the data were processed

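The study measured where histone octamers settled on purified DNA in a test tube, with and without CpG methylation. DNA from 3 human and 3 mouse bacterial artificial chromosomes (BACs, large cloned inserts kept in bacteria) was pooled by species. CpG methylation was added with the bacterial methyltransferase M.SssI at 2 units per µg DNA, per the labels' protocols. Methylated or unmethylated DNA was reconstituted with chicken erythrocyte core histones at a DNA to histone mass ratio of 5 to 1 by dialysis from 2.0 to 0.01 M NaCl over 16 hours. Because DNA was in excess, histones were assembled in competition between sequences. The product was digested with 1 Worthington unit of micrococcal nuclease (MNase), which cuts linker DNA, for 5 minutes, and mononucleosome-length fragments were recovered from a gel. Naked-DNA controls were cut with 0.3 Worthington units of MNase or sonicated to about 150 bp, and sized between 140 and 160 bp. The 14 libraries were barcoded, amplified by 7 PCR cycles and sequenced as SOLiD read pairs in 1 run, so no sequencing batch separates them. The labels state that the nucleosome samples are biological replicates made on separate days.

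The authors deposited, for each library, a whole-number count of reads at every base of every clone. These counts are not normalized, and no read falls in the outermost bases of a clone, as for fragment midpoints. The submitters' processing notes name the builds hg19 and mm9 and the program DESeq without versions; the aligner and read filters are not given in the sources used here. Coordinates in the files are clone coordinates, counted from 1 at the start of each insert, and are given here as such with the clone names of the files (halb, hmyc and hp53 for human, malb, mmyc and mp53 for mouse). No genome sequence was used here, so genes, exons, CpG islands and GC content were not analysed here.

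The authors also deposited a signal per base for each state, combined over replicates: 3 bp sums scaled to a mean of 1 read per base and averaged with equal weight. Their position tables list 11448 human and 13741 mouse positions with a CpG number each, and a naked-DNA table lists 12884 mouse positions. The length of the stretch over which CpG were counted is not given in the sources used here. At every listed nucleosome position the higher of the combined signals was at least 10.003. Neighbouring positions lay a median of 22 bp apart, so most overlap and are not independent nucleosomes. The authors' deposited tables give an adjusted p-value for each position, which was used only to compare call lists.

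The deposited tables meant for DESeq hold a scaled signal, not raw reads. In 100% of their values the signal was a whole number of reads, within 0.001, once multiplied by the library's mean reads per base. Those reads equalled the 3 bp sum at the base where the combined profile of the library's own state peaked within 5 bp of the listed position, for 100% of human and at least 99.9927% of mouse values. At the listed base itself only 75.5% to 87.7% were equal. The methylated and unmethylated libraries are thus read at bases that can differ by a few bp. In the human position table the headings of the methylated and unmethylated columns disagree with the combined profiles: 100% of the values headed as methylated equalled the profile marked unmethylated, within 0.002. The table's own fractional difference follows the profiles, as 100% of its values equalled methylated minus unmethylated over the larger, within 0.002, in both species. The state of each library was taken from its labels and the direction of the authors' calls from the fractional difference, so the headings do not enter the values given here.

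The planned test had assumed raw counts in those tables. It was run instead on the same reads taken from the deposited per-base counts. Methylated and unmethylated nucleosome libraries were compared in each species with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 fold changes are methylated over unmethylated. CPM are counts scaled by edgeR to the TMM-scaled reads in the features tested, which are the listed positions or, for windows, all windows. The filter kept 11426 human and 13152 mouse positions. DESeq2 1.42.0 and limma 3.58.1 were used for alternatives. Summaries used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

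Relations along the clones were measured with Spearman's rho, and p came from 10000 random circular shifts inside each clone, which keep the spacing of positions. The smallest p these shifts can give is 0.0001. Shares of reads per library were compared by exact permutation of the labels inside each species, summing both species over 60 assignments, two-sided. The smallest joint p is 0.0167, and the human or mouse libraries alone cannot go below 0.1 or 0.333. Shares per CpG class, profile correlations and position shifts used reads at the listed base for all libraries. Naked digests were compared over 13 bp at the authors' naked-DNA positions with at least 20 summed reads, with a pseudocount of 0.5; they have 1 library per state and no test between states.

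Library totals ranged from 156676 to 1847590 reads, or 0.235 to 2.77 reads per base. Counting intervals are exact (Clopper-Pearson, 95%), and a count of 0 was bounded by 3 reads over the group. Both cover counting error only, because reads had no molecular identifiers. The tests were checked on simulated counts with 100 features changed 2-fold and 100 changed 4-fold. For human positions (11426 tested), 2% of 2-fold and 36.7% of 4-fold changes were recovered; for mouse positions (13152 tested), 2.2% and 11.5%. With 147 bp tiles, 59% of 2-fold and 99% of 4-fold changes were recovered in human (3822 tiles), and 29% and 98% in mouse (4445 tiles). Unchanged features called were 1 human and 0 mouse positions, and 13 human and 9 mouse tiles. The simulation drew each feature independently and left out overlap between positions and differences that run through a whole library. These counts of false calls therefore cannot be carried over to the real libraries. The circular-shift test gave p under 0.05 in 8 of 100 human and 2 of 100 mouse series without an effect, and in 100 of 100 with a planted slope.

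Before the data were examined, the groups, the tests, most alternatives and the rule for named positions were fixed. Named positions are, per species, the 10 largest rises and 10 largest falls among called positions whose methylated libraries all lie above or all below every unmethylated library, none within 147 bp of another, the length taken here as a nucleosome length. Named windows are the 3 windows of 10 kb with the smallest p. Replicate numbers did not establish pairs: human deviations from the group means correlated at 0.202 and 0.23 for numbers 1 and 2, only 2 pairs exist, and mouse deviations correlated at -0.177. Alternatives covered scaling, test, filter, threshold, tiling, spacing, the replicate number as a block and each library left out. The CpG number was taken from the authors' column in place of a count from sequence, and classes of CpG number replaced the planned classes of exons, promoters and CpG islands. The class of 5 or more CpG was chosen after the data were seen.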

Results

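The data comprised 14 libraries. From human clones there were 3 unmethylated and 2 methylated nucleosome libraries, 1 MNase digest and 1 sonicated sample of unmethylated naked DNA. From mouse clones there were 2 unmethylated and 2 methylated nucleosome libraries, 1 MNase digest of each state and 1 sonicated unmethylated sample. The human clones spanned 223154 bp (halb), 181231 bp (hmyc) and 167314 bp (hp53), and the mouse clones 238557 bp (malb), 195673 bp (mmyc) and 233459 bp (mp53). Unmethylated human nucleosome replicates 1, 2 and 3 held 1301500, 523931 and 444006 reads, and methylated replicates 1 and 2 held 868603 and 885424. Unmethylated mouse nucleosome replicates 1 and 2 held 1847590 and 1091164 reads, and methylated replicates 1 and 2 held 600763 and 264011. The naked MNase digests held 501367 reads in human, 720664 in unmethylated mouse and 346935 in methylated mouse DNA. The sonicated samples held 324152 reads in human and 156676 in mouse.

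One comparison asked whether CpG methylation changed nucleosome occupancy according to the number of CpG at a position. Occupancy of methylated relative to unmethylated DNA rose with CpG number in both species. Human positions without CpG had a median log2 fold change of -0.18 (2908 positions, quartiles -0.76 and 0.36), those with 3 to 4 CpG 0.16 (2121 positions), those with 5 to 8 CpG 0.28 (949 positions) and those with 9 or more CpG 0.70 (183 positions, quartiles -0.33 and 1.54). The corresponding mouse medians were -0.20, 0.10, 0.23 and 0.86, over 2864, 2717, 895 and 128 positions. Positions with 9 or more CpG thus had a median 1.62-fold higher occupancy on methylated human DNA and 1.82-fold higher on methylated mouse DNA, although only 67.8% of the human and 71.1% of the mouse positions in this class had a positive log2 fold change. The sign of every class median was the same under 4 scalings of the libraries, although the mouse median with 3 to 4 CpG was only 0.001 with library size alone. Spearman's rho between CpG number and log2 fold change was 0.162 in human and 0.144 in mouse, across positions that overlap and are not independent. Permutation by circular shifts gave 95% intervals of 0.038 to 0.075 in human and -0.023 to 0.018 in mouse, and p = 0.0001 in each species, the smallest they can give. The shifts do not cover variation between libraries. Unmethylated human replicates 1 and 2 do not differ in methylation, yet rho was 0.172 for the ratio of these single libraries over 13 bp. On the same measure, pairs of human libraries between states gave 0.066 to 0.234, with 0.066 and 0.116 for unmethylated replicate 2. The human group fold change over 13 bp gave 0.202. Within single clones rho was 0.0894 in halb, 0.110 in hmyc, 0.143 in hp53, 0.137 in malb, 0.0992 in mmyc and 0.180 in mp53, each with a permutation p of 0.0001; these fits of single clones were chosen after the data were seen.

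**Figure D1:**
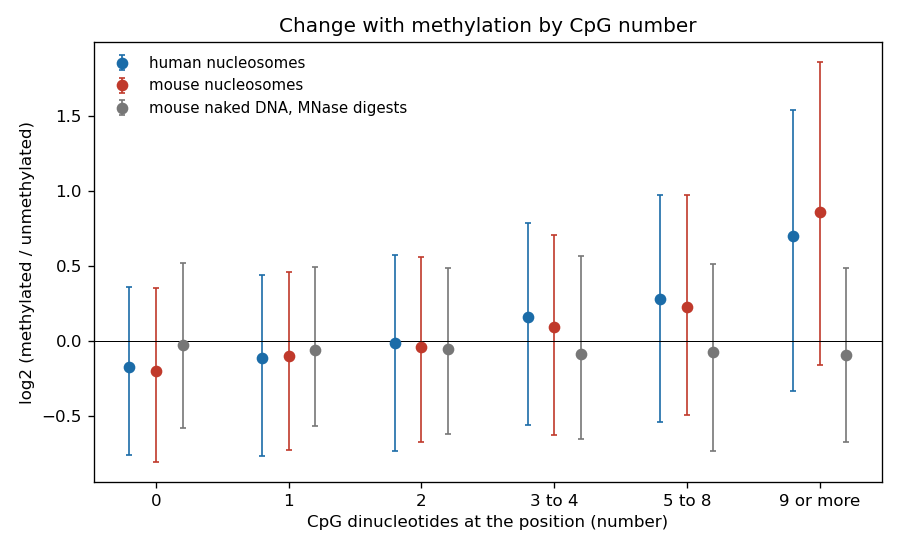
Median log2 ratio of methylated to unmethylated DNA (vertical axis) by the number of CpG at the position (horizontal axis), for human nucleosomes, mouse nucleosomes and MNase digests of naked mouse DNA at the naked-DNA positions; points are medians over positions and bars the quartiles. The nucleosome medians rose from -0.18 and -0.20 without CpG to 0.70 and 0.86 with 9 or more, while the naked medians lay between -0.09 and -0.03. The naked medians cover a different set, positions with at least 20 naked reads, of which 36 had 9 or more CpG. At mouse nucleosome positions with at least 20 naked reads, the nucleosome median was -0.42 without CpG and -0.14 with 9 or more.

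The same relation was measured per library as the share of reads at CpG-rich positions. In human, positions with 5 or more CpG took 9.99% ± 0.46 (SD, n = 2) of the reads at listed positions in the methylated libraries and 7.88% ± 0.67 (SD, n = 3) in the unmethylated ones. In mouse they took 9.46% ± 1.04 (SD, n = 2) and 7.17% ± 0.44 (SD, n = 2). All 4 methylated libraries lay above all 5 unmethylated libraries of their own species. Positions with 9 or more CpG took 1.57% ± 0.08 of methylated and 1.07% ± 0.12 of unmethylated human reads, and 1.38% ± 0.48 and 0.589% ± 0.082 in mouse (SD, same n). Positions with 1 CpG took less: 26.9% ± 0.2 against 28.4% ± 0.1 in human and 26.5% ± 1.1 against 27.838% ± 0.005 in mouse. Naked MNase digests had 7.82% of reads at positions with 5 or more CpG in human, and 6.04% (unmethylated) and 5.81% (methylated) in mouse; sonicated DNA had 8.61% and 7.49%.

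The difference in share at 5 or more CpG, summed over both species, was 4.398 percentage points (exact permutation p = 0.0167, the smallest of 60 assignments), and the difference between species was not past the test (exact permutation p = 0.883). With each clone weighted equally, the summed difference was smaller, at 3.554 points (exact permutation p = 0.0167). The means were then 9.85% methylated and 8.28% unmethylated in human, and 8.29% and 6.30% in mouse. Over the 6 separate CpG classes the adjusted p (Benjamini-Hochberg) was 0.05 for the classes of 1, 3 to 4, 5 to 8 and 9 or more CpG, which is not under the threshold, 0.06 for no CpG and 0.567 for 2 CpG. Over 13 bp the adjusted p was 0.04 for every class except 2 CpG, and at the peak of each state it was 0.0501 to 0.08 for the same classes, so this call turns with the counting. Without any 1 of the unmethylated human libraries the exact permutation p was 0.0556, the smallest that the remaining 36 assignments can give, so these fits could not pass. Without unmethylated mouse replicate 2 it was 0.0667 (exact permutation over 30 assignments, smallest 0.0333), with a difference of 4.09 points.

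**Figure D2:**
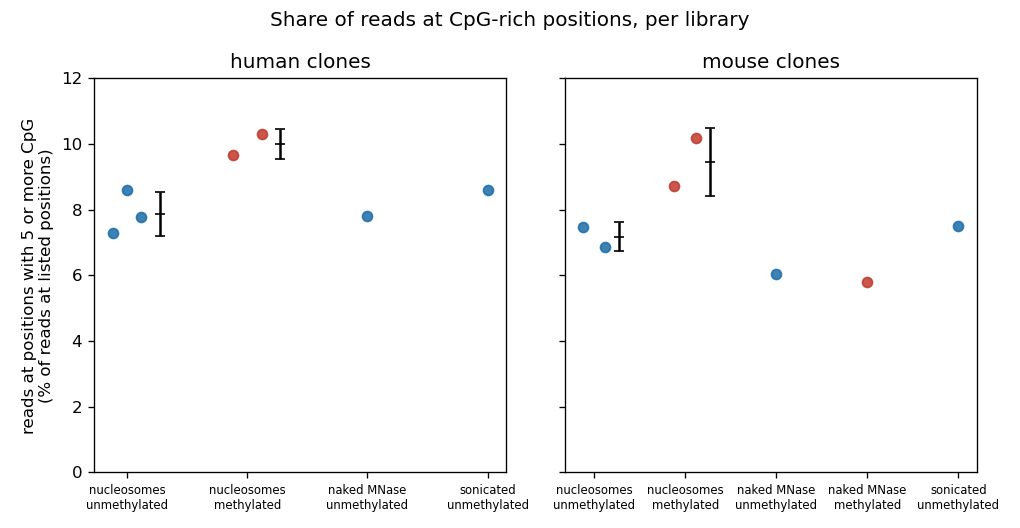
Share of reads at listed positions that fell at positions with 5 or more CpG (vertical axis, percent) for each library of the human and mouse clones, by kind of sample; each point is 1 library and the black bars are the mean and SD of the nucleosome groups. Methylated nucleosome libraries lay between 8.72% and 10.3%, and unmethylated ones between 6.86% and 8.60%.

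Position by position, 379 of 11426 human positions differed between methylated and unmethylated nucleosomes (edgeR quasi-likelihood test, adjusted p under 0.05), 197 higher and 182 lower on methylated DNA. The higher positions were rich in CpG, with a mean of 4.71 CpG against 2.46 in circular shifts of the calls (95% interval 2.17 to 2.80, permutation p = 0.0001, the smallest possible). The lower positions had a mean of 2.03 CpG against 1.81 in shifts (permutation p = 0.121). Shifts of the calls likewise do not cover variation between libraries, so these p-values do not tell methylation from differences between preparations. By class, 23 of the 183 positions with 9 or more CpG were called higher and 7 lower, while 6 of the 2908 without CpG were higher and 42 lower. By clone, hp53 held 123 higher and 46 lower calls, hmyc 48 and 70, and halb 26 and 66. The count and the balance of directions rested on single libraries: there were 2 higher and 0 lower calls without unmethylated replicate 1, 915 and 1010 (1925 in all) without unmethylated replicate 2, 17 and 3 without unmethylated replicate 3, 14 and 1 without methylated replicate 1, and 7 and 0 without methylated replicate 2. Tiles of nucleosome length gave 23 higher and 6 lower calls and limma 63 and 8. The limma fit also changed the scaling, to mean reads per base of each library without TMM. Its median log2 fold change over all positions was 0.265, against -0.0243 in the main fit, so its balance does not reflect the test alone. Scaling by library size alone gave 188 higher and 268 lower calls, and the replicate number as a block gave 605 and 618. TMM scaling separately in each clone gave 208 higher and 241 lower calls.

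The 10 human positions named for the largest rise included 5 in one stretch of clone hmyc, with 6 to 14 CpG each. There, hmyc_156133 had 141 methylated reads over both libraries and 6 unmethylated reads over 3 (log2 fold change 4.52 ± 0.62 SE, edgeR adjusted p = 0.0044), and hmyc_153744 had 179 and 9 (4.31 ± 0.59, adjusted p = 0.0044). At hmyc_151942 the 31 methylated reads stood against 1 unmethylated read, a depth-corrected ratio of 33.2 with a counting interval of 5.53 to 1351.61; hmyc_152530 had 38 reads against 2 and hmyc_154178 had 36 against 2. Elsewhere, hmyc_74758 rose with 319 reads against 27 (3.79 ± 0.52, adjusted p = 0.0044) and hp53_57445 with 121 against 11 (3.57 ± 0.60, adjusted p = 0.0091). The remaining named rises were hp53_99791 (55 reads against 3), hp53_67909 (38 against 2) and hp53_51295 (32 against 2).

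The 10 human positions named for the largest fall had 1 to 4 CpG and 1 to 3 methylated reads each. The most deeply read was hp53_144208, with 75 unmethylated reads against 3 methylated ones, a depth-corrected ratio of unmethylated to methylated of 23.4 (counting interval 7.70 to 116). Its neighbour hp53_144508 had 56 against 3 (ratio 17.5, counting interval 5.67 to 87.2). At halb_143211 the counts were 51 and 1, at halb_200641 47 and 2, at hmyc_141113 47 and 2, at hmyc_132645 36 and 2, at hp53_76942 46 and 1, at hp53_57741 46 and 2, at hp53_79514 36 and 2, and at hp53_106003 38 and 2. Of the 20 named human positions, 3 kept an adjusted p under 0.05 without methylated replicate 2 (of 20 tested), and 1 did without unmethylated replicate 1 (of 14 tested).

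**Figure D3:**
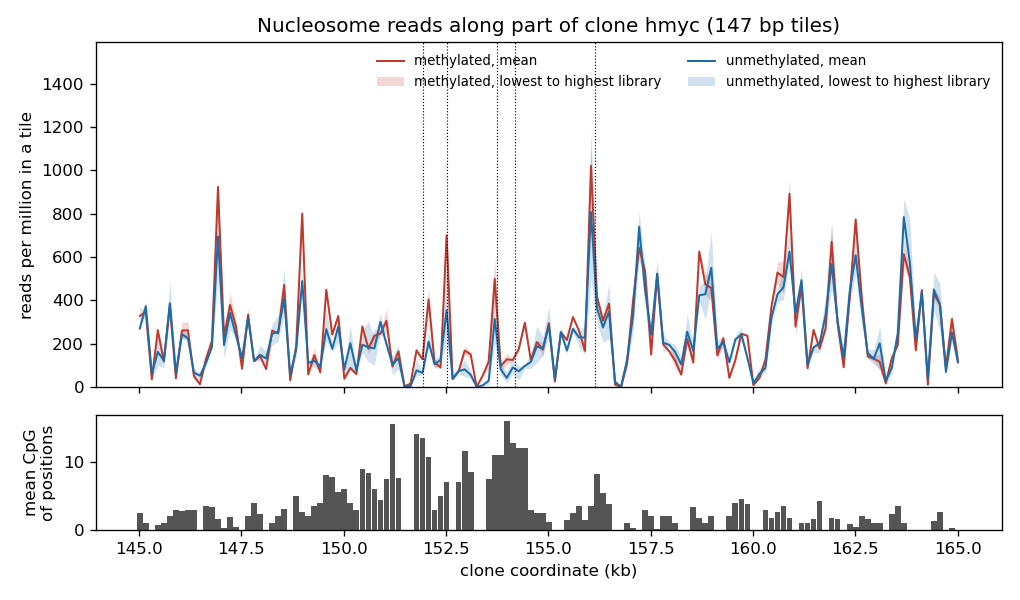
Nucleosome reads scaled to the total of each library in consecutive tiles of nucleosome length along part of human clone hmyc (upper panel; lines are means of 2 methylated and 3 unmethylated libraries, shading the lowest to highest library, dotted lines the named positions) and the mean CpG number of listed positions in each tile (lower panel; a tile without listed positions has no bar), against the clone coordinate in kb. The 5 named rises lie in or beside the stretch where the CpG number is highest.

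In mouse, 33 of 13152 positions differed between the states (edgeR, adjusted p under 0.05), 31 higher and 2 lower on methylated DNA. The 31 higher positions had a mean of 6.48 CpG, against 1.94 in circular shifts (95% interval 1.29 to 2.71, permutation p = 0.0001, the smallest possible). Of these, 9 were among the 128 positions with 9 or more CpG and none among the 2864 without CpG. As in human, the shifts do not cover variation between libraries. By clone, mp53 held 16 higher and 1 lower call, malb 10 and 1, and mmyc 5 and 0. There were 45 higher and 29 lower calls without unmethylated replicate 1, 16 and 2 without unmethylated replicate 2, 17 and 1 without methylated replicate 1, and 0 of either without methylated replicate 2. When both states were read over the same 13 bp there were 160 higher and 45 lower calls, at the listed base 67 and 23, and with DESeq2 72 and 8. Of the 33 positions, 33 were called over 13 bp, 22 with DESeq2, 23 with limma and 17 with a mean count of at least 20, all in the same direction. All 33 had groups that did not overlap, so a change of direction was hardly possible in fits of the same reads.

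Among the 10 mouse positions named for the largest rise, 3 lay close together in malb with 11 CpG each. At malb_158518 there were 19 methylated reads and 0 unmethylated reads in both libraries, so occupancy was at least 18.0-fold higher against a floor of 3 reads over the unmethylated group; this leaves out the counting error of the methylated reads, and the counting interval of the ratio begins at 13.25. At malb_158090 there were 35 reads against 3 (ratio 33.1, counting interval 10.4 to 168), and at malb_159160 there were 20 against 2 (ratio 28.4, counting interval 6.90 to 251). In mmyc, mmyc_42598 (4 CpG) rose with 42 reads against 6 (log2 fold change 4.24 ± 0.79 SE, edgeR adjusted p = 0.0184), and mmyc_40120 (7 CpG) had 23 against 3. The position richest in CpG among the named ones, mp53_153976 with 17 CpG, rose with 39 reads against 6 (4.07 ± 0.79, adjusted p = 0.0199). The others were mp53_28912 (55 against 2), malb_74951 (35 against 5), mp53_82839 (62 against 13) and mp53_39450 (57 against 12). Both falls were at deeply read positions: mp53_77171 with 6 CpG had 82 methylated reads against 1714 unmethylated ones (-3.05 ± 0.52, adjusted p = 0.0085), and malb_237443 with 1 CpG had 22 against 483 (-3.12 ± 0.60, adjusted p = 0.0189).

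The authors' deposited table listed 2595 human positions with an adjusted p under 0.05, 1719 higher and 876 lower on methylated DNA. For mouse, the authors' deposited table listed 349, of which 310 were higher and 39 lower. All 379 human and all 33 mouse positions called by edgeR were among them in the same direction. The deposited tables meant for DESeq hold the same reads, so this overlap is no independent check. Of the authors' calls, 99.3% in human and 89.7% in mouse had the same sign in edgeR. The rest may include positions left out by the filter. The positions listed as higher had a mean of 2.89 CpG in human and 4.38 in mouse, and those listed as lower 1.82 and 1.59, in the authors' deposited table.

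Over larger regions no 10 kb window passed the test: 0 of 59 in human and 0 of 68 in mouse (edgeR), with 6 and 1 at an unadjusted p under 0.05, and 0 in both with DESeq2. The human windows with the smallest p were hp53 90001 to 100000 (log2 fold change 0.25 ± 0.06 SE), halb 110001 to 120000 (-0.28 ± 0.09) and hp53 70001 to 80000 (0.24 ± 0.08), each at an edgeR adjusted p of 0.3. In mouse they were mp53 60001 to 70000 (0.16 ± 0.06), mmyc 20001 to 30000 (-0.17 ± 0.06) and mmyc 1 to 10000 (-0.15 ± 0.06), each at an edgeR adjusted p of 0.678. Without unmethylated human replicate 2, 41 of 59 human windows were called, and without methylated mouse replicate 1, 14 of 68 mouse windows were. At whole-clone scale, halb took 29.5% ± 0.9 (SD, n = 2) of methylated and 33.5% ± 3.4 (SD, n = 3) of unmethylated human reads (exact permutation p = 0.3), and hp53 took 33.5% ± 0.91 and 29.4% ± 2.7 (SD, same n; exact permutation p = 0.2). For each mouse clone the exact permutation p was 0.667. The libraries of a single species are too few for this test to reach its threshold. No human or mouse clone could therefore have passed, and no conclusion is drawn from these p-values.

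Whether called positions gather into stretches was tested on each position and its next neighbour, and this test was not past its threshold. In human, 15 of 379 called positions (3.96%) had their next tested neighbour at least a nucleosome length away called in the same direction, against a mean of 2.95% in circular shifts (one-sided permutation p = 0.150). Without unmethylated replicate 2 the human share was 12.8% (one-sided permutation p = 0.0791), and without any other human library it was 0%. In mouse it was 2 of 33 (6.06%) against 2.33% (one-sided permutation p = 0.181). Among the windows of 5 kb richest in CpG, hmyc 150001 to 155000 held 10 of the 48 higher calls in its clone and malb 155001 to 160000 held 4 of 10, but hp53 145001 to 150000 held 3 of 123 and mp53 60001 to 65000 held 0 of 16; these counts were not tested.

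The naked DNA controls asked whether methylation alters MNase cutting without histones, and had 1 library per state. At 11567 mouse positions with at least 20 reads, the log2 ratio of methylated to unmethylated had a median of -0.05 and an SD of 0.97. At 2941 positions (25.4%) the ratio exceeded 2-fold, 1486 higher and 1455 lower, where counting error alone would give 510. The split was not even at positions with at least 50 reads, with 261 higher and 609 lower. The ratio showed little relation to CpG number, with rho = -0.022 across positions. At nucleosome positions with 5 or more CpG, the naked share at the listed base was 0.962 times as high on methylated as on unmethylated DNA (counting interval 0.919 to 1.01). Over 13 bp the naked shares were 6.06% methylated and 5.84% unmethylated, so the direction turned with the counting. With 9 or more CpG the ratio at the listed base was 1.24 (counting interval 1.018 to 1.503), against 2.35 between the mean nucleosome shares. Those means cover unequal libraries. Methylated replicates 1 and 2 had 1.041% and 1.724%, and unmethylated replicates 1 and 2 had 0.647% and 0.531%. The ratio between the lowest methylated and the highest unmethylated library is therefore smaller than 2.35 and nearer the naked ratio.

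Across mouse nucleosome positions, the nucleosome log2 fold change correlated with the naked log2 ratio at rho = 0.129 (permutation p = 0.0001, the smallest possible). This positive relation was not seen at more deeply read positions, and at the most deeply read ones its sign was reversed. At positions with at least 50 naked reads rho was -0.0566 (permutation p = 0.0063), and at those with at least 20 it was -0.0094 (permutation p = 0.482). A position without naked reads receives a log2 ratio of 1.14 from the pseudocount because the libraries differ in depth; leaving out the 374 of 13152 positions of this kind gave rho = 0.117 (permutation p = 0.0001). Of the 1023 tested positions with 5 or more CpG, 304 had at least 20 naked reads. Among positions with at least 20 naked reads the median nucleosome log2 fold change was -0.42 without CpG, -0.33 with 1, -0.26 with 2 and -0.19 with 3 to 4. It was -0.11 with 5 to 8 CpG and -0.14 with 9 or more (19 positions). Every class median, including that of the class richest in CpG, thus lay below 0 there, while the medians still rose up to 5 to 8 CpG. Without methylated replicate 2 rho was 0.0454.

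At the listed base, profiles of nucleosome libraries were on average more alike within a state than between states, compared as Pearson's r of log2 (count + 1) across positions. In human, the methylated pair had r = 0.901, the 3 unmethylated pairs a mean of 0.692 (0.623 to 0.772) and the 6 pairs between states a mean of 0.521 (0.428 to 0.621). In mouse, r was 0.695 in the methylated pair, 0.747 in the unmethylated pair and 0.50 on average between states (0.348 to 0.605). In human the lowest unmethylated pair and the highest pair between states were nearly equal, and the order did not hold in wider counting. Over 13 bp, unmethylated human replicate 2 had r = 0.698 and 0.717 with the methylated libraries against 0.694 and 0.640 with unmethylated replicates 1 and 3. In tiles of nucleosome length it had 0.942 and 0.941 against 0.893 and 0.904, and mouse unmethylated and methylated replicates 1 had 0.935, above the 0.915 of the methylated pair. With naked digests, r at the listed base was 0.298, 0.006 and 0.26 for the unmethylated human replicates 1, 2 and 3, and -0.035 and -0.107 for the methylated ones. In mouse it was 0.18 to 0.206 for unmethylated and -0.156 to 0.022 for methylated libraries. Mean r with sonicated DNA was 0.091 in human and 0.083 in mouse at the listed base, but 0.81 and 0.777 in tiles, where mean r with naked digests was 0.469 and 0.526. The methylated and unmethylated naked digests of mouse DNA had r = 0.727. Unmethylated human replicate 2 had r = 0.609 and 0.621 with the methylated libraries, above the 0.428 to 0.532 of unmethylated replicates 1 and 3.

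Shifts of position between the states overlapped those between unmethylated replicates in human and were slightly more frequent in mouse; no test was made. Between the combined methylated and unmethylated profiles, the highest 3 bp sum within 30 bp moved by more than 10 bp at 22.4% of human and 24.3% of mouse positions, with a median movement of 1 bp. Between single libraries of opposite state this share was 25.8% (23.2% to 29.4%) in human, against 23.8% (21.7% to 26.5%) between unmethylated replicates and 13.5% in the methylated pair. In mouse it was 27.5% (24.3% to 32.3%) between states, 23.5% in the unmethylated pair and 22.3% in the methylated pair, so all 4 mouse pairs between states lay above both pairs within a state.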

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

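All alternatives given for the CpG relation, leaving out libraries in the share, window, profile, shift, clustering and naked-DNA results, reading both states at the listed base or over 13 bp, reading shares at each state's own peak, limma, DESeq2 on windows and over 13 bp, the crossed pairing and the scaled pseudocount, the lower naked minimum and leaving out positions without naked reads were chosen after the data were seen. The rise with CpG number kept its direction in all 18 human alternatives (rho 0.0894 to 0.381) and all 17 mouse ones (0.0992 to 0.316); p was 0.0001 throughout, the smallest the shifts can give, so it cannot rank them. Classes by GC content and the observed to expected CpG ratio, and exon, intron and CpG island classes, were not run because no sequence or annotation was used here. The share at 5 or more CpG differed by 3.66 to 5.14 points when 1 library was left out; p was 0.0556 without each unmethylated human library, where no smaller p is possible, 0.0667 without unmethylated mouse replicate 2 and 0.0333 to 0.0417 otherwise.

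Counts of called positions did depend on the processing, and except where stated the cause was not tested. In human the 379 calls became 111 with a mean count of at least 20, 1047 at adjusted p under 0.1, 29 of 3822 tiles of nucleosome length, 22 with positions at least a nucleosome length apart (fewer were tested), 1390 at the listed base, 71 with limma, and 2 to 1925 with 1 library left out. In mouse the 33 calls became 50 with DESeq2 size factors, 80 with the DESeq2 Wald test, 71 with a mean count of at least 20, 64 at adjusted p under 0.1, 5 of 4445 tiles, 10 with positions at least a nucleosome length apart, 90 at the listed base, 205 over 13 bp, 159 with DESeq2 over 13 bp, and 0 to 74 with 1 library left out. DESeq2 gave no adjusted p to 7992 mouse positions. No called or named position changed direction in any alternative that tested it. This is weak evidence of stability, because all 379 human and all 33 mouse calls had groups that did not overlap. Leaving out a library or rescaling the same reads could therefore hardly turn a direction. Named positions missed their threshold in 74 of 314 human and 30 of 177 mouse fits. Where leaving out a library left 1 in an arm, that library was assumed to vary like the others; mouse clustering has no value without methylated replicate 2, where nothing was called.

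The replicate number as a block, with pairs not established, gave 1223 human and 41 mouse calls. Because same-numbered mouse libraries deviated in opposite directions, the crossed pairing was also fitted and gave 415 calls, 260 higher and 155 lower. With 2 libraries per state, the correlations of the 2 pairings (-0.177 and 0.177) must be equal with opposite sign. The crossed pairing was thus picked from the same data, and its higher count is no evidence of pairs. With the block, 0 windows of 10 kb were called, as without it, and the 2 mouse windows of 5 kb became 0.

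Called 10 kb windows ranged from 0 to 41 in human and 0 to 14 in mouse with 1 library left out, and 2 mouse windows of 5 kb were called. Mean r between states rose to 0.900 (human) and 0.87 (mouse) in tiles, and to 0.626 in human over 13 bp. With at least 50 naked reads, 870 of 5303 positions exceeded 2-fold, 261 higher and 609 lower, and the median log2 ratio was -0.185. The naked relation was -0.0566 with at least 50 reads and -0.0094 with at least 20, 0.0912 with the pseudocount scaled to library size, and 0.117 without the positions that had no naked reads; the cause was not tested. The share of positions shifted became 26.5% (human) and 29.1% (mouse) with a search of 50 bp, and 28.4% and 30.5% for shifts over 5 bp, a looser criterion; with 1 library left out it was 21.8% to 25.2% and 23.5% to 28.9%. In simulated counts at the depth of these libraries, 2-fold changes were recovered at 2% of simulated human positions but in 59% of human tiles.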

Other observations

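The test on calls at the listed base was chosen before its result was seen; the other tests in this part were chosen after the results were seen. The windows of 5 kb with the highest mean CpG number were examined as regions, ranked on CpG alone. In each of the 6 such windows, 3 per species, every methylated library had a higher CPM than every unmethylated library. This order was not particular to them: it was found in 25 of all 116 human windows, of which 16 lay among the 34 of hp53, and in 23 of all 135 mouse windows, while the reverse order was found in 16 and 22. In human, hmyc 150001 to 155000 (mean 8.21 CpG over 78 positions) had 5920 ± 626 CPM on methylated (SD, n = 2) and 4154 ± 1044 on unmethylated DNA (SD, n = 3), hp53 90001 to 95000 had 10236 ± 92 and 8451 ± 174, and hp53 145001 to 150000 had 10462 ± 511 and 7786 ± 1860. None of the 3 passed the edgeR test (adjusted p 0.26 to 0.342). In mouse, mmyc 40001 to 45000 (mean 7.32 CpG over 59 positions) rose from 3108 ± 227 to 4572 ± 819 CPM (SD, n = 2 each; log2 fold change 0.55 ± 0.15 SE, edgeR adjusted p = 0.0138). The only other mouse window of 5 kb past the test, mp53 40001 to 45000, had the smaller adjusted p (edgeR 0.0114; log2 fold change 0.53 ± 0.13 SE) and was not among the 3 richest in CpG. The other CpG-rich mouse windows were mp53 60001 to 65000 (9210 ± 506 against 7066 ± 281 CPM, edgeR adjusted p = 0.142) and malb 155001 to 160000 (4826 ± 257 against 4166 ± 182 CPM, edgeR adjusted p = 0.558). With the replicate block, 0 of 135 mouse windows of 5 kb were called, 17 were called without methylated replicate 1, and none was called without unmethylated replicate 1, unmethylated replicate 2 or methylated replicate 2.

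Methylated nucleosome libraries also concentrated their reads on fewer bases. After thinning every library to 156676 reads, the most used 1% of bases held 40.1% ± 2.8 (SD, n = 2) of methylated and 32.0% ± 4.7 (SD, n = 3) of unmethylated human reads, and 40.7% ± 2.9 and 30.2% ± 2.5 (SD, n = 2 each) in mouse (exact permutation p = 0.0333 over 60 assignments). Naked digests held 28.6% to 33.2% and sonicated DNA 11.6% and 14.0%. Nucleosome libraries had a repeat of about 10 bp along the DNA: the autocorrelation at 10 bp exceeded the mean of those at 5 and 15 bp by 0.066 to 0.129, while in naked digests it lay below by -0.042 to -0.07. The score was 0.111 on methylated and 0.095 on unmethylated DNA in human, and 0.082 and 0.119 in mouse, where both methylated libraries lay below both unmethylated ones. Because the species went opposite ways, the test on their sum (exact permutation p = 0.567) does not speak to either alone.

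The rise with CpG number could come from reading each state at its own peak, from MNase preference or from the preparation of the libraries. Reading both states over the same 13 bp argues against the first, since rho was 0.202 in human and 0.175 in mouse, above the circular-shift intervals (0.05 to 0.089 and -0.023 to 0.021). At the listed base the naked ratio at 5 or more CpG, 0.962, lay below the lowest ratio between single mouse nucleosome libraries, 1.165. With 9 or more CpG the naked ratio was 1.24 (counting interval 1.018 to 1.503). Over 13 bp the naked shares at 5 or more CpG were 6.06% methylated against 5.84% unmethylated. These values and 1 naked library per state keep MNase preference open. Reads at listed positions made up 40.6% to 52.7% of unmethylated and 58.35% to 62.1% of methylated human libraries. In mouse they made up 44.1% to 49.96% and 58.6% to 63.05%. Across nucleosome libraries of each species, the share at 5 or more CpG rose as r with the unmethylated naked digest fell. Among unmethylated human libraries, replicate 2 was nearest the methylated ones here. The naked ratio cannot test a naked-like background that differs between preparations, which stays open. A GC bias that differs between preparations cannot be told apart from the state, because GC content was not held fixed and unmethylated human replicates 1 and 2, equal in methylation, already differed with an absolute rho of 0.172 against a lowest value of 0.066 between states. A preference of histones for methylated CpG-rich DNA, the biological difference the design names, stays open beside these.

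Unmethylated human replicate 2 was closer to the methylated libraries than replicates 1 and 3 were, and without it the calls went from 379 to 1925. Unequal shares of the clones could raise its correlation, as it had 29.6% of its reads in halb against 36.0% and 34.9% in replicates 1 and 3. Inside single clones, over 13 bp, both of its r with the methylated libraries still exceeded all 4 of the others in 3 of 3 clones. This argues against the share of reads per clone as the only source of the order. The gap was narrow, however: its lower r was 0.708 against their highest of 0.696 in halb, 0.727 against 0.713 in hmyc and 0.653 against 0.617 in hp53. Over all clones it was 0.698 against 0.659, so the share of reads per clone may account for part of the gap. A mislabelled sample may be considered: its highest r with a methylated library, 0.621, lay below its 0.681 with unmethylated replicate 1 and far below the human methylated pair (0.901), but below the mouse methylated pair (0.695) only by about the SD of unmethylated pairs (0.075). Its share at 5 or more CpG, 8.60%, lay between the other unmethylated (7.28% and 7.77%) and the methylated libraries (9.67% and 10.3%), while in tiles it was closer to the methylated libraries (0.942 and 0.941 against 0.893 and 0.904), so a wrong label stays open and, as all 3 libraries carry the same label, no biological explanation was tested.

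Reading both states at the listed base gave 1390 human calls against 379. The listed base may be the peak of 1 state only, which would lower the count of the other. Of the 1011 added calls, 76.0% had the peak of the lower state away from the listed base, against 44.5% of all tested positions. This lies between the bounds set beforehand, at least 90% or no more than the share over all positions, so it may account for part of the added calls, and the rest stays open.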
